A study of Mus musculus with 19 samples.

How the data were processed

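RNA-seq was measured in 9 libraries of B cells sorted by flow cytometry from mouse spleen. Follicular (FO) B cells are the main recirculating B cell population, and B-1a cells are a self-renewing population that carries CD5. Each cell type was taken from mice carrying the R26CA(Ebf1/+) allele without Cre (2 libraries per cell type, called the controls here). It was also taken from Cd79a-Cre R26CA(Ebf1/+) mice (2 libraries per cell type), in which Cre in B lineage cells should switch on Ebf1 from the Rosa26 locus. The ninth library came from FO B cells labelled Cd23-Cre Ebf1(fl/–), a genotype in which Cre acts in mature B cells on a floxed Ebf1 allele opposite a null allele. Its strain label is mixed C57BL/6 and 129, whereas the other 8 libraries are labelled C57BL/6. EBF1 ChIP-seq was measured in 2 libraries of wild-type FO B cells from lymph node, with a home-made antibody. Input chromatin was measured in 8 runs of 5 libraries of wild-type mature B cells from lymph node, enriched on magnetic beads. ChIP-seq and input samples of pro-B cells were not analysed here.

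Per the labels' protocols, poly(A) RNA was fragmented by heat, copied from random hexamers and given a dUTP-marked second strand, so the libraries keep the strand. The deposited RNA-seq files hold raw read counts per gene. Per the submitters' processing notes, Bowtie 12.5 (written so), TopHat 1.3.1, HTSeq 0.5.3 and the mouse build mm9 were used, and the strand setting of the counting is not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore be assigned wrongly, which leaves the MHC, interferon-induced and ribosomal protein families less certain than single-copy genes. The files hold 21025 gene entries, of which 20657 (98.2%) matched a RefSeq accession of the GRCm38 reference table, used for names alone, and 375 entries share a symbol with another. Reads without a gene (12.8 to 37.1% of each library) and ambiguous reads (0.379 to 0.614%) were left out of library sizes and tests. The deposited ChIP-seq and input files hold positions of single aligned reads on mm9 as the authors' alignment gave them, not counts per region, and peak lists were not used here. Reads were 36 bp long, and 34 bp in 1 input run.

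Genes with at least 1 CPM in at least 2 libraries were kept (11420 genes). Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, robust, in R 4.3.3) with a coefficient per group over all 9 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The single Cd23-Cre Ebf1(fl/–) library is assumed to vary like the other groups. The design text states that the RNA-seq libraries are biological replicates apart from that single library, and counts within each group differed by more than sampling noise (chi-square per degree of freedom 212 in FO controls, 46.2 in FO Cd79a-Cre, 60.4 in B-1a controls and 163 in B-1a Cd79a-Cre).

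The library numbers in the labels fall into 2 ranges, and each group of 2 has 1 library in each range. These are called library series 1 (5 libraries, with the Cd23-Cre Ebf1(fl/–) library) and series 2 (4 libraries). The pairing check compared deviations from the group means over 8416 genes. Libraries of the same series deviated together, with correlations of 0.695 to 0.913 in all 6 pairs of groups, so the numbers pair the libraries. The size of the series difference varied between groups. Its SD on the log2 scale was 0.930 in FO controls, 0.441 in FO Cd79a-Cre, 0.574 in B-1a controls and 0.867 in B-1a Cd79a-Cre. A series term assumes the same difference in every group, so it may not remove all of it. A fit with the series as a term (a replicate block) was listed before the data were examined, as were the main test, the gene lists, the naming rule and most alternatives. Results of the series-term fit are given beside the unblocked ones where they differ in a call or in a count by over 1.5 times. After the data were seen, a further fit was added with a bias score as covariate. Its direction is the first component of the deviations from the group means over genes with a mean log2 CPM of at least 3, which holds 89.0% of that variance. The score of a library is its projection on this direction after centring over all 9 libraries, so it also holds differences between groups and, for the single Cd23-Cre Ebf1(fl/–) library, that library's own difference from the others. DESeq2 1.42.0, with and without the series term, was an alternative tool. Other alternatives were RLE and total-count scaling, other filters, a fold threshold of 1.5, fits of the compared groups alone and leaving out each library in turn.

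The text names genes by a rule. For each comparison it takes the 12 largest fitted folds in each direction among called genes with a mean of at least 10 CPM in the higher group, without immunoglobulin or T cell receptor segments and numbered clone symbols, and up to 4 members of each list with the smallest p. The rule was applied to the unblocked fit for the comparisons of B-1a with FO cells and to the series-term fit for Cd79a-Cre in B-1a cells and for the Cd23-Cre Ebf1(fl/–) library. It was applied to the bias-score fit for Cd79a-Cre in FO cells and for the difference between the cell types, where the other edgeR fits called 0 genes, and those choices of fit were made after the data were seen. Genes named outside the rule are said to be so.

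Of 26 gene lists, 24 had enough measured members and were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, with adjustment over the lists of a comparison. The B cell lists covered markers of B-1, follicular and marginal zone cells, B cell receptor signalling, inhibitory receptors, early EBF1 target genes, transcription factors, survival and NF-kB genes, Toll-like receptors, trafficking receptors, MHC class II and costimulation, and plasma cell genes. General lists covered the cell cycle, immediate early genes, heat shock, interferon response and ribosomal proteins. Markers of T, NK, monocyte, neutrophil, dendritic and erythroid cells and sex-linked genes checked the sort and the libraries, as did a list of platelet markers that had too few expressed members for a test. Ighd, Hba-a1, Hba-a2 and Ahsp were list members without a gene entry of that symbol. The log2 CPM used a prior count of 2. Comparisons that share control libraries were set against 20 simulations of unchanged groups. A gene with 0 counts in the lower group is given as at least a fold against 3 counts over that group, and with 1 to 3 counts as a ratio of summed counts with an interval from the exact (Clopper-Pearson) 95% binomial limits. Intervals and floors cover counting error only, since reads carry no molecular identifiers.

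For ChIP-seq, 1 read per position and strand was kept, read ends were shifted to the fragment centre, and counts in windows of 200 bp at steps of 50 bp were tested one-sided (Poisson) against the largest of the genome-wide rate and local rates over 1000, 5000 and 10000 bp of the pooled input. Windows at q under 0.01 were merged within 200 bp, and a region was shared when regions of both libraries overlapped. After the data were seen, shared regions were also described apart from those where the input exceeded 5 times its genome mean. The fold over input compares shares of all kept positions, with 1 position added to the input. The caller was written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. On simulated libraries the caller recovered 0%, 4% and 58% of sites enriched 5-, 10- and 20-fold (100 sites of each), with 0 false regions. ChIP background and input were drawn there at the same rates, so false regions at places of high input were not tested. Assignment of regions to genes and a motif search were not run, because no mm9 genome or annotation was used here.

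The RNA-seq tests were tested on simulated counts for the 11420 genes with 200 genes changed and the library bias kept. For Cd79a-Cre in FO cells the unblocked fit recovered 0%, 13.4% and 47.0% of 2-, 4- and 8-fold changes, the series-term fit 32.8%, 79.1% and 90.9%, and the bias-score fit 64.2%, 85.1% and 93.9%. False calls there numbered 0, 2 and 30, so in this simulation the bias-score fit called more false genes than its threshold allows. In the real data that fit called 1757 genes higher and 1419 lower in B-1a than in FO controls, far more than the 200 changed here. Whether such group differences, which the score also holds, alter its recovery and false calls was not tested. For the Cd23-Cre Ebf1(fl/–) comparison the unblocked fit recovered 0% at each of these folds, and the series-term fit 5.97%, 68.7% and 80.3% with 0 false calls.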

Results

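Gene expression was measured by RNA-seq in 9 libraries of mouse splenic B cells to follow what extra or missing EBF1, a transcription factor required for B lineage commitment, does in mature B cells. FO B cells and B-1a cells were each represented by 2 control libraries, R26CA(Ebf1/+) without Cre, and 2 Cd79a-Cre R26CA(Ebf1/+) libraries. A single library of FO B cells was labelled Cd23-Cre Ebf1(fl/–) and has no replicate. Reads counted in genes numbered 13389608 and 18615148 in the FO controls, 13531411 and 19932985 in FO Cd79a-Cre, 8220659 and 13389538 in the B-1a controls, 10112699 and 18612800 in B-1a Cd79a-Cre, and 8434630 in the library labelled Cd23-Cre Ebf1(fl/–). Between 12677 and 14107 genes had a read in a library. Cd74, the invariant chain of MHC class II, was the most abundant gene in 8 libraries, with 0.937 to 4.12% of gene reads. EBF1 binding was measured by ChIP-seq in 2 libraries of wild-type FO B cells with 5325486 and 16251102 aligned reads, against 5 input libraries.

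Ebf1 itself was detected in every library. It stood at 233 and 330 CPM in the FO controls, 405 and 364.8 CPM in FO Cd79a-Cre, 190 and 225 CPM in the B-1a controls and 261 and 294 CPM in B-1a Cd79a-Cre. The log2 difference between Cd79a-Cre and control was 0.47 ± 0.18 (SE) in FO cells (edgeR with the series term, adjusted p = 1) and 0.42 ± 0.18 in B-1a cells (adjusted p = 0.635). Neither passed the test adjusted over all genes, and the difference was positive in both series of both cell types. Taken as a single gene chosen beforehand, Ebf1 had unadjusted edgeR p-values of 0.0312 in FO and 0.0489 in B-1a cells with the series term. These were 0.133 and 0.159 unblocked, and 0.00608 and 0.00337 with the bias score. The library labelled Cd23-Cre Ebf1(fl/–) had 443 CPM, a log2 difference of 0.76 ± 0.23 from the FO controls (adjusted p = 0.346 with the series term, 0.0267 with the bias score). The Ebf1 count covers the whole gene and so does not check whether the floxed part was deleted. Directions drawn from that library rest on its label.

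**Figure D1:**
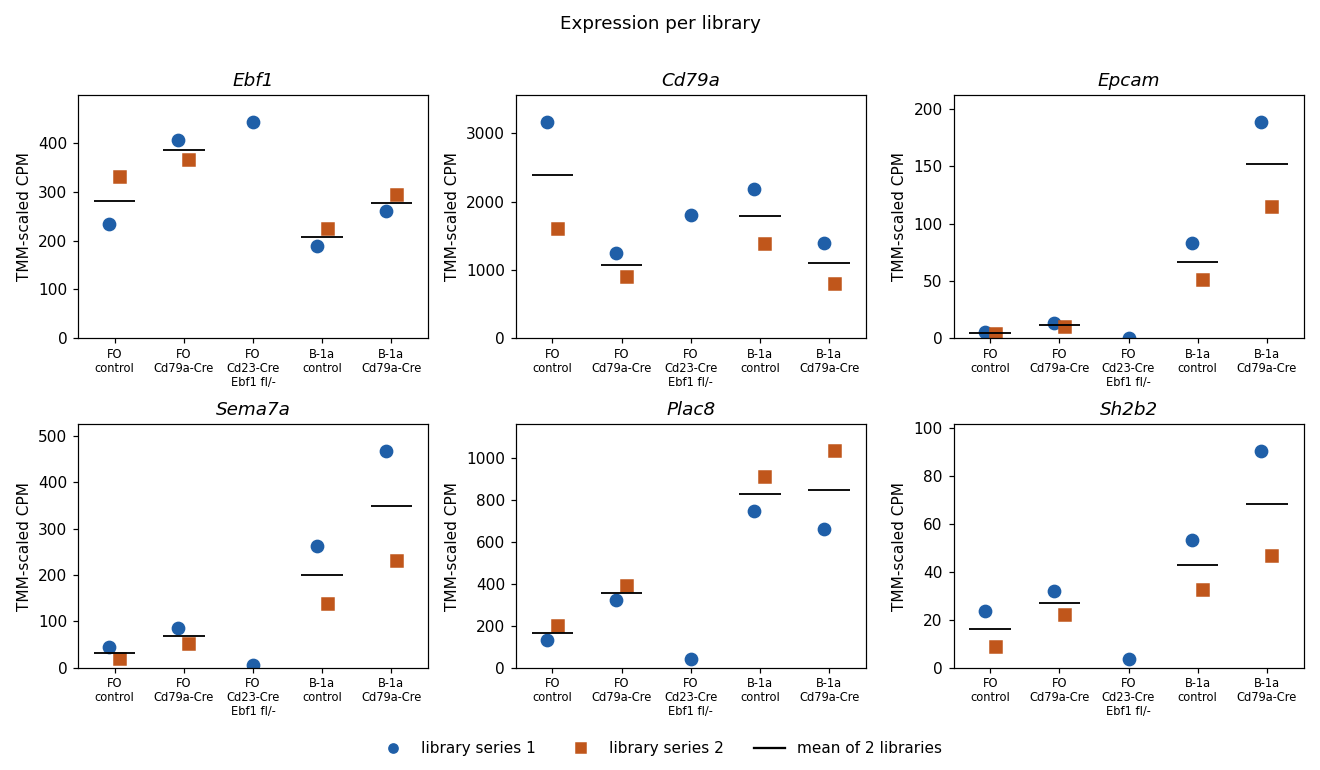
Expression of Ebf1, Cd79a, Epcam, Sema7a, Plac8 and Sh2b2 in CPM (y axes) in each of the 9 RNA-seq libraries, shown as points by group with library series 1 and 2 marked. Ebf1 lies between 190 and 443 CPM, and Epcam ranges from 0.656 CPM in the library labelled Cd23-Cre Ebf1(fl/–) to 189 CPM in a B-1a Cd79a-Cre library.

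The comparison of B-1a with FO control cells asked how these B cell types differ without the transgene. Among the genes higher in B-1a cells, Il10, an anti-inflammatory cytokine, had 302 counts in B-1a and 0 in FO libraries (at least 141-fold higher), and Tnfsf4, the OX40 ligand, had 367 counts against 1 (ratio 513, interval 91.5 to 20325). Robo1, a receptor for Slit guidance cues, was at least 116-fold higher (249 counts against 0), and Fras1, an extracellular matrix protein, had 1758 counts against 1 (ratio 2458, interval 441 to 97156). Cyp11a1, the enzyme that starts steroid hormone synthesis from cholesterol, had 840 counts against 3 (ratio 392, interval 134 to 1903). FO cells had more Fcer2a, which encodes CD23 (log2 difference −4.58 ± 0.47, adjusted p = 0.0108). They also had more Ccr6, a chemokine receptor (−3.81 ± 0.66, adjusted p = 0.0376), and Icosl, the ligand of the costimulatory receptor ICOS (−3.78 ± 0.28, adjusted p = 0.00681).

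Other genes higher in B-1a cells were the actin regulators Wipf3 (log2 7.90 ± 1.03) and Pstpip2 (7.24 ± 0.50), the serine protease Prss23 (7.57 ± 1.16) and the small GTPase Rab3b (7.15 ± 0.91). So were the glycolipid enzyme B4galt6 (7.08 ± 0.37) and Nyx, a leucine-rich proteoglycan. Tcerg1l had 260 counts against 2 (ratio 182, interval 49.8 to 1509). Genes higher in FO cells included the calcium channel Ryr2 (−5.96 ± 0.98), Tmem108 (−5.20 ± 0.41), Fam101b (−4.80 ± 0.28), the peptidase Cpm (−4.44 ± 0.75) and the zinc finger gene Zfp608 (−4.31 ± 0.60). They also included the sterol hydroxylase Cyp27a1 (−4.28 ± 0.38), Emid1 (−4.00 ± 0.58), the transcription factor Sox4 (−4.00 ± 0.72) and the actin-severing protein Gsn (−3.93 ± 0.58). In total edgeR called 236 genes higher and 117 lower in B-1a cells, and 929 higher and 674 lower with the series term, where all 353 unblocked calls were called too. Without the first B-1a control library 4 were called higher and 0 lower, and without the first FO control 5 and 4.

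Among the B cell lists, B-1 cell markers were higher in B-1a cells in 18 of 19 members. Of these, 10 were called higher, and 13 when adjusted over the list alone. They included Ctla4, an inhibitory receptor (5.99 ± 0.73), Ahr, the aryl hydrocarbon receptor (4.63 ± 0.38), the phospholipid scramblase Plscr1 (3.71 ± 0.50) and Nt5e, the ecto-nucleotidase CD73 (3.50 ± 0.47). The list as a whole was higher by camera (median 2.88, adjusted p = 2.3e-15), and the call was lost with an estimated correlation (adjusted p = 0.0806). Follicular markers were lower as a list (median −1.44, adjusted p = 0.000151; adjusted p = 0.0867 with an estimated correlation). Of 11 members 1 was called lower, Fcer2a, and 6 adjusted over the list alone, among them Cd40 (−1.77) and the IL-4 receptor gene Il4ra (−1.66). Of 15 MHC class II and costimulation genes, 2 were called lower, Icosl and the MHC class II transactivator Ciita (−1.47 ± 0.28, adjusted p = 0.0461). Adjusted over the list alone, 8 were lower and 1 was higher, the costimulatory ligand Cd80 (4.45 ± 0.94). That list was lower (median −1.07, adjusted p = 1.7e-05; adjusted p = 0.0806 with an estimated correlation). Plasma cell genes were higher (median 0.60, adjusted p = 0.0020; adjusted p = 0.102 with an estimated correlation). Of 15 members 2 were called, also when adjusted over the list alone, namely Prdm1, which encodes the plasma cell factor BLIMP-1 (3.93 ± 0.29, adjusted p = 0.00681), and the immunoglobulin J chain gene Igj (3.44 ± 0.66, adjusted p = 0.0498).

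Other B cell lists held called members without a shift of the list in the unblocked fit. Of 13 marginal zone markers, Cd9, a tetraspanin (3.30 ± 0.45), and Marcks, a kinase substrate at the membrane (1.47 ± 0.26), were called higher. Adjusted over the list alone, 3 were higher and 1 was lower, the Notch target Hes1 (camera adjusted p = 0.221). Of 17 inhibitory receptor genes, 3 were higher, namely Fcrl5 (3.86 ± 0.66), the phosphatase gene Ptpn22 (3.04 ± 0.58) and Cd5 (2.88 ± 0.49), and Cd22 was lower (−1.74 ± 0.23). Adjusted over the list alone, 4 were higher and 3 lower. The list's median was −0.25, its mean 0.29 and its test downward (adjusted p = 0.645). Among 26 transcription factors, Zbtb20 (3.76 ± 0.53) and Nfatc1 (2.26 ± 0.36) were higher and Bcl6, a germinal centre repressor, was lower (−2.82 ± 0.27). Adjusted over the list alone, 4 were higher and 6 lower (list adjusted p = 0.270). Of 23 trafficking receptors, the integrin gene Itgb1 (2.76 ± 0.39) and the adhesion receptor gene Cd44 (1.93 ± 0.35) were among 3 called higher, and Ccr6 and the oxysterol receptor gene Gpr183 (−1.74 ± 0.29) were lower. This list had 4 higher and 3 lower adjusted over the list alone (list adjusted p = 0.969). Vpreb3 was the single called member of 12 early EBF1 target genes (−3.62 ± 0.57, also adjusted over the list alone), a list with adjusted p = 0.191. Irak3, an inhibitor of Toll-like receptor signalling, was the single call among 16 Toll-like receptor genes (−2.10 ± 0.39, also adjusted over the list alone; list adjusted p = 0.452). In the unblocked fit none of 29 B cell receptor signalling genes (list adjusted p = 0.242) or of 23 survival and NF-kB genes (list adjusted p = 0.763) was called by edgeR, over all genes or adjusted over the list alone.

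The general lists and the markers of other cells were read in the same comparison and fit. Heat shock genes were higher as a list (median 0.95, adjusted p = 0.00438; adjusted p = 0.175 with an estimated correlation). Of 9 members Hspa8, a constitutive chaperone (1.10 ± 0.25), was called when adjusted over the list alone. Interferon response genes were lower (median −0.66, adjusted p = 0.000134; adjusted p = 0.210 with an estimated correlation). Of 20 members 1 was called, the signal transducer Stat2 (−1.18 ± 0.23), and 3 adjusted over the list alone. Of 20 immediate early genes, Myc (1.87 ± 0.33) and Atf3 were called higher, and 3 adjusted over the list alone (list adjusted p = 0.242). Atf3 differed between the B-1a control libraries, at 4.54 and 48.35 CPM. No member of 26 cell cycle genes (list adjusted p = 0.242) or of 39 ribosomal protein entries (median −0.08, mean 0.17, upward test, adjusted p = 0.763) was called. T cell markers were lower (median −0.80, adjusted p = 0.000606; adjusted p = 0.0867 with an estimated correlation). Thy1 was called of 20 (−1.83 ± 0.34), and 5 were lower and 1 higher adjusted over the list alone. NK markers were also lower (median −1.64, adjusted p = 6.4e-05; adjusted p = 0.175 with an estimated correlation). The perforin gene Prf1 was called of 12 (−2.29 ± 0.38), and 3 were lower adjusted over the list alone. Monocyte (17 members, adjusted p = 0.221), neutrophil (9, 0.348), dendritic (7, 0.221), erythroid (8, median 0.07, mean −0.05, downward test, 0.649) and sex-linked lists (5, 0.763) had 0 called members by edgeR. Of these, only Flt3 of the dendritic markers was called when adjusted over the list alone (−2.21).

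More list members of this comparison were called with the series term. Of the receptor signalling genes 2 were higher, among them the Src family kinase gene Blk (0.86 ± 0.15, adjusted p = 0.00552). A further 5 were lower, among them the exchange factor gene Rasgrp3 (−3.11 ± 0.42), Cr2 (−2.50 ± 0.28) and the adaptor gene Pik3ap1 (−1.04 ± 0.17), and the numbers were unchanged when adjusted over the list alone. Of the survival and NF-kB genes 3 were higher, among them the kinase gene Pim1 (1.99 ± 0.24), and 4 were lower, among them Traf5 (−1.06 ± 0.17) and the BAFF receptor gene Tnfrsf13c (−0.89 ± 0.15). These were 7 and 5 adjusted over the list alone. MHC class II genes had 2 higher and 12 lower members, follicular markers 7 lower, B-1 markers 13 higher and plasma cell genes 6 higher and 1 lower. In that order these were 2 and 12, 8, 16, and 10 and 1 adjusted over the list alone. Transcription factors had 4 higher and 10 lower (5 and 10 adjusted over the list alone), marginal zone markers 5 and 2 (7 and 4), Toll-like receptor genes 3 and 1 (6 and 1), and inhibitory receptors 4 and 4 (4 and 5). Trafficking receptors had 5 higher and 4 lower (5 and 5), immediate early genes 5 and 2 (6 and 2), and early EBF1 target genes 1 and 2 in both counts. Heat shock genes had 5 higher, interferon genes 6 lower (8 adjusted over the list alone), T cell markers 2 higher and 5 lower (3 and 9) and NK markers 5 lower (7). Cell cycle genes had 2 higher, among them the cyclin gene Ccne1 (1.12 ± 0.20), and ribosomal protein genes 2 higher and 1 lower. Flt3 was the single dendritic marker called lower and Mpo, the myeloperoxidase gene, the single neutrophil marker called lower. Among the lists the neutrophil markers were the single change of call, lower with the series term (median −0.98, camera adjusted p = 0.00543; adjusted p = 0.326 with an estimated correlation). Median and mean differed in sign for inhibitory receptors (−0.23 and 0.34, downward test) and ribosomal proteins (−0.05 and 0.25, upward test), and the sex-linked list had a median of 1.51 with a downward test.

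The same comparison between the Cd79a-Cre groups asked whether the cell types still differed with the transgene. B-1a Cd79a-Cre cells had more Fras1 (7.52 ± 0.68), Etl4 (7.45 ± 0.41, adjusted p = 0.00278), the ephrin receptor gene Ephb4 (7.44 ± 1.3, adjusted p = 0.0463), Wipf3 (7.22 ± 0.99) and Cdkn2a, which encodes cell cycle inhibitors (6.55 ± 0.94, adjusted p = 0.0207). Kndc1 had 320 counts against 0 (at least 124-fold higher), Tnfsf4 543 against 3 (ratio 210.3, interval 71.6 to 1023) and Tcerg1l 321 against 2 (ratio 186, interval 51.2 to 1546). Kbtbd10 (6.50 ± 1.12), the ubiquitin ligase gene Cblc (6.46 ± 1.13), the malic enzyme gene Me3 (6.44 ± 0.92) and Prss23 (6.30 ± 1.01) completed the 12 largest. FO Cd79a-Cre cells had more Zfp608 (−6.77 ± 0.68, adjusted p = 0.00877), Cpm (−6.48 ± 0.84), the kinase gene Lrrk2 (−6.33 ± 1.05), Fcer2a (−5.44 ± 0.49), and Fam101b (−5.42 ± 0.29). They also had more Trim36 (−5.37), the collagen gene Col27a1 (−5.30), the corepressor gene Tle1 (−5.28), Tmem108 (−5.22), the chromatin organiser Satb1 (−4.97 ± 0.44), Sox4 (−4.89) and Dennd3 (−4.74 ± 0.38).

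B-1 markers were again higher as a list (median 2.81, camera adjusted p = 4.2e-14; adjusted p = 0.0957 with an estimated correlation). Of 19 members 7 were called, and 14 adjusted over the list alone, among them the myosin gene Myo1d (4.58). Follicular markers were lower (median −1.30, adjusted p = 0.000186; adjusted p = 0.0957 with an estimated correlation). Of 11 members 2 were called, Fcer2a and the transcriptional repressor gene Bach2 (−2.38 ± 0.43), and 7 adjusted over the list alone. MHC class II genes were lower (median −0.90, adjusted p = 8.6e-05; adjusted p = 0.0957 with an estimated correlation). Icosl (−4.18), H2-Eb2 (−2.56), Ciita (−1.59) and the peptide loading gene H2-DMb1 (−1.34) were called of 15, and 6 were lower and 1 higher adjusted over the list alone. Plasma cell genes were higher (median 0.49, adjusted p = 0.00689; adjusted p = 0.143 with an estimated correlation). Interferon response genes (median −1.02, adjusted p = 8.6e-05; adjusted p = 0.253 with an estimated correlation), T cell markers (median −0.63, adjusted p = 0.00689; adjusted p = 0.143 with an estimated correlation) and NK markers (median −1.19, adjusted p = 0.00065; adjusted p = 0.267 with an estimated correlation) were lower. Marginal zone markers were higher as a list (median 1.12, adjusted p = 0.0393; adjusted p = 0.562 with an estimated correlation). The series-term fit called 15 of 19 B-1 markers higher, 8 of 11 follicular markers lower and, of the MHC class II genes, 2 higher and 12 lower. Neutrophil markers were then lower as a list (median −1.03, adjusted p = 0.00832; adjusted p = 0.395 with an estimated correlation). edgeR called 240 genes higher and 173 lower, and 1020 and 890 with the series term. Without either FO Cd79a-Cre library 0 were called in both directions.

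Cd79a-Cre in B-1a cells asked what changed with Cre and the transgene together in this cell type. Every Cd79a-Cre library carries both and no control carries Cre, so effects of EBF1, Cre and the Cd79a insertion cannot be told apart. With the series term the chemokine gene Ccl22, which encodes a ligand of CCR4, rose by 4.64 ± 0.36 on the log2 scale (adjusted p = 0.00592), from 7.73 and 8.75 CPM to 338.86 and 140.54 CPM. Igf1r, the receptor for insulin-like growth factor 1, fell by 3.14 ± 0.29 (adjusted p = 0.0103), from 59.0 and 59.6 CPM to 5.84 and 7.70 CPM, while the FO controls had 4.17 and 7.84 CPM. The R-spondin receptor gene Lgr6 (5.90 ± 0.72, adjusted p = 0.0166), Pitpnm3 (5.71 ± 0.65, adjusted p = 0.0128) and the secreted glycoprotein gene Fstl1 (4.41 ± 0.44, adjusted p = 0.0104) rose. The inhibitory receptor gene Ctla4 (−2.43 ± 0.38, adjusted p = 0.0372), the transcription factor gene Stat4 (−2.42 ± 0.31, adjusted p = 0.0199) and Satb1 (−1.96 ± 0.19, adjusted p = 0.0104) fell.

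The other named genes that rose in B-1a Cd79a-Cre cells were the membrane repair gene Dysf (4.14 ± 0.53), Ephb4 (3.61 ± 0.45), the potassium channel gene Kcnk3 (2.98 ± 0.44), the calcium channel gene Cacna1h (2.54 ± 0.34), the folate hydrolase gene Ggh (2.13 ± 0.24) and the adenosine kinase gene Adk (2.07 ± 0.21). The forkhead gene Foxf2 had 242 counts against 1 (ratio 187, interval 33.3 to 7418) and Pgbd5 343 against 3 (ratio 88.4, interval 29.99 to 431). Those that fell were the MAP kinase phosphatase gene Dusp4 (−3.16 ± 0.35), the zinc transporter gene Slc30a4 (−2.54 ± 0.36), the kinesin gene Kif13a (−2.36 ± 0.27) and Ipcef1 (−2.14 ± 0.25). So did the chromatin remodeller gene Chd3 (−2.11 ± 0.24), the diacylglycerol kinase gene Dgkh (−2.0 ± 0.33), the receptor gene Gpr171 (−1.97 ± 0.31) and the sphingosine phosphate phosphatase gene Sgpp2 (−1.82 ± 0.24).

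By list, the single called B-1 marker was Ctla4, with Nt5e (−1.07) also lower adjusted over the list alone. The single called receptor signalling gene was the exchange factor Vav3 (−1.67 ± 0.28, adjusted p = 0.0494) and the single called transcription factor was Bcl6 (−1.20 ± 0.20, adjusted p = 0.0484). Follicular markers had Fcer2a (−0.93) and Bach2 (−0.91) lower when adjusted over the list alone. With the series term, camera called heat shock genes lower (0 of 9 members above 0, median −0.40), MHC class II genes lower (median −0.16), immediate early genes lower (median −0.40) and marginal zone markers higher (median 0.33), each with adjusted p = 0.0494. Each was lost with an estimated correlation (adjusted p = 0.722). Adjusted over the list alone, 3 MHC class II members were lower (H2-Eb2 −0.82, Icosl −0.73 and Ciita −0.56) and the sphingosine phosphate receptor gene S1pr3 was the single marginal zone marker higher (1.10). In the unblocked fit camera called the transcription factor list (median −0.21) and the sex-linked list (median −1.78) lower, each with adjusted p = 0.0491 and each lost with an estimated correlation (adjusted p = 0.629). The sex-linked call cannot be told apart from mouse sex, since the Y-linked Ddx3y was almost absent in 1 B-1a Cd79a-Cre library. edgeR called 22 genes higher and 30 lower with the series term. The unblocked fit called 0 in both directions (lowest adjusted p = 0.485). It had 313 genes at an unadjusted p under 0.05, fewer than chance alone gives. DESeq2 called 16 and 31. Without the first B-1a control library, the series-term fit called 1 gene in each direction.

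Cd79a-Cre in FO cells asked the same of the follicular type. In the fit with the bias score, which was chosen after the data were seen, the epithelial adhesion molecule gene Epcam (1.46 ± 0.16, adjusted p = 0.00812), Sema7a, which encodes a membrane-anchored semaphorin (1.41 ± 0.13, adjusted p = 0.00407), the adaptor gene Sh2b2 (1.08 ± 0.14, adjusted p = 0.0279) and Plac8, a B-1 marker of the lists (1.03 ± 0.10, adjusted p = 0.00407), rose. Cd79a, which encodes the Ig-alpha chain of the B cell receptor and is the locus of the Cre, fell by 0.93 ± 0.10 (adjusted p = 0.00843), and the IL-9 receptor gene Il9r fell by 1.10 ± 0.16 (adjusted p = 0.0484). Each of these named genes moved in the same direction within both library series, with Epcam at 1.11 and 1.47, Plac8 at 1.28 and 0.98, and Cd79a at −1.34 and −0.845. They were selected by calls from the same libraries, so this is not an independent check. Another gene called higher by this fit, named below, was not higher within either series. In B-1a cells Cd79a also fell in that fit (−0.88 ± 0.10, adjusted p = 0.00240).

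Without that covariate edgeR called 0 genes in either direction in FO cells. The unblocked fit had 72 genes at an unadjusted p under 0.05 and the series-term fit 286, with lowest adjusted p-values of 1 and 0.137. Chance alone would put a share of 0.05 of the 11420 genes there, which is more than either count. The same holds for every count of unadjusted p given for the other comparisons, so these counts are no sign of changed genes. The bias-score fit called 7 higher and 2 lower. DESeq2 called 1 higher and 0 lower, and 11 and 2 with the series term, a fit added after the data were seen. On counts simulated for this comparison the bias-score fit made 30 false calls, beside 43, 57 and 62 recovered genes changed 2-, 4- and 8-fold. The gene called by DESeq2 without the series term, named after its values were seen, was Ccl22 (3.16 ± 0.67, adjusted p = 0.0263), with 1.85 and 0.83 CPM in the controls and 17.16 and 6.89 CPM with Cre. With the series term and adjusted over the list alone, Plac8 passed among B-1 markers (adjusted p = 0.00162) and Cd79a among receptor signalling genes (adjusted p = 0.00331). MHC class II genes were lower as a list (camera, median −0.24, adjusted p = 0.025; adjusted p = 0.596 with an estimated correlation). Sex-linked genes were lower too (camera, adjusted p = 0.0383, and 0.884 with an estimated correlation). The Y-linked Ddx3y stood at 0.05 CPM in 1 FO and 1 B-1a Cd79a-Cre library and at least 22.42 CPM in the other 7. By the sex-linked list the low libraries were those of series 2 (series 2 minus series 1, −7.79 in FO and −6.93 in B-1a Cd79a-Cre). Mouse sex by Y-linked reads was thus not matched between Cre and control in series 2. The list call cannot be told apart from this.

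The difference between the Cre effects of both cell types was tested as an interaction. In the bias-score fit, Igf1r responded more negatively in B-1a than in FO cells by −3.08 ± 0.29 (adjusted p = 0.00699), Slc30a4 by −2.46 ± 0.25 (adjusted p = 0.00699), Ipcef1 by −2.26 ± 0.24 (adjusted p = 0.00699) and Satb1 by −1.71 ± 0.19 (adjusted p = 0.00720). Hpse, which encodes heparanase, was the single gene with a more positive response in B-1a cells (1.3 ± 0.17, adjusted p = 0.0136). That fit called 1 gene higher and 14 lower. On counts simulated for this comparison it made 19 false calls, beside 33, 48 and 60 recovered genes changed 2-, 4- and 8-fold. The unblocked fit called 0 in both directions with 128 genes at an unadjusted p under 0.05, and the series-term fit 0 with 551. Both counts are fewer than chance alone gives. DESeq2 called 0 higher and 2 lower, named after their values were seen, Igf1r (−3.15 ± 0.59, adjusted p = 0.000894) and Kif13a (−2.32 ± 0.51, adjusted p = 0.0305). With the series term DESeq2 called more genes in both directions, as given below, with Cacna1h, Fstl1 and Ggh more positive in B-1a cells. The heat shock list was called by camera in the unblocked fit (adjusted p = 0.011; adjusted p = 0.832 with an estimated correlation), and 0 lists were called with the series term.

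The library labelled Cd23-Cre Ebf1(fl/–) was compared with the FO controls to ask what differs in FO cells labelled as lacking Ebf1. With the series term, Plaur, the urokinase receptor gene, fell by 5.04 ± 0.32 on the log2 scale (adjusted p = 0.000967), from 86.0 and 58.1 CPM to 2.49 CPM. Cr2, which encodes the complement receptor CD21, fell by 2.98 ± 0.39 (adjusted p = 0.0226), from 265.67 and 874.58 CPM to 38.55 CPM. Fcer2a had 2547.95 CPM against 1083.69 and 1523.55 CPM (1.27 ± 0.24, adjusted p = 0.0876 over all genes and 0.00264 adjusted over the list alone). Spn, which encodes the sialoprotein CD43 of B-1 and plasma cells, rose by 2.36 ± 0.19 (adjusted p = 0.00262), from 116 and 68.7 CPM to 566 CPM, near the 594.5 and 414 CPM of the B-1a controls. Dok2, an inhibitory adaptor, rose by 4.05 ± 0.53 (adjusted p = 0.0226).

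The other genes named by the rule that fell were the elongation factor gene Ell3 (−4.97 ± 0.37, adjusted p = 0.00197), Eps8l1 (−5.88 ± 0.81), Stac2 (−5.80 ± 0.55), the stearoyl-CoA desaturase gene Scd1 (−3.29 ± 0.37), and Sema7a (−3.00 ± 0.30). So did the potassium channel gene Kcnk5 (−2.85 ± 0.29), Mrgpre (−2.64 ± 0.27), Hopx (−2.50 ± 0.40), Sh2b2 (−2.40 ± 0.37) and Slamf1 (−2.20 ± 0.25). Those that rose were Osgin1 (3.05 ± 0.45), the phospholipid transfer protein gene Pltp (2.78 ± 0.28), Ttbk1 (2.49 ± 0.35), the p38-gamma kinase gene Mapk12 (2.22 ± 0.26) and the galectin gene Lgals3 (2.17 ± 0.31). So did the basement membrane gene Nid1 (2.05 ± 0.30), Tmem66 (1.89 ± 0.28), the sugar transporter gene Slc2a6 (1.75 ± 0.26), the Src family kinase gene Fgr (1.67 ± 0.22) and Sorcs2 (1.66 ± 0.26). edgeR with the series term called 16 genes higher and 27 lower. The unblocked fit called 0 in both directions (lowest adjusted p = 0.128), with 372 genes at an unadjusted p under 0.05, and DESeq2 called 17 and 29. The strain label and the genotype of this single library cannot be separated. It lies in series 1 alone, and the series term assumes the same series difference in every group. That difference was largest in the FO controls (SD 0.930 on the log2 scale), so part of it may remain in this comparison. Without the first FO control 9 were called higher and 14 lower, and without the second 42 lower.

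By list in the series-term fit, B cell receptor signalling genes were lower (median −0.21, camera adjusted p = 0.0388; adjusted p = 0.322 with an estimated correlation), with Cr2 and the calcium release channel gene Itpr1 (−1.85 ± 0.26, adjusted p = 0.0291) called of 29. Among B-1 markers Spn rose and Plac8 fell (−1.72 ± 0.23, adjusted p = 0.0245), with 1 higher and 4 lower adjusted over the list alone. Among marginal zone markers Hes1 (−2.13 ± 0.28, adjusted p = 0.0226) was 1 of 2 called lower, and 4 were lower adjusted over the list alone. The marginal zone list had a median of 0.04 and a mean of −0.45, and the inhibitory receptor list 0.03 and −0.47. MHC class II genes were higher in 14 of 15 members (median 0.51, mean 0.03, adjusted p = 0.00034; adjusted p = 0.249 with an estimated correlation). Plasma cell genes were lower (adjusted p = 0.0236; adjusted p = 0.349 with an estimated correlation), with Prdm1 (−1.42) and Igj (−3.34) lower and Sdc1, the syndecan CD138, higher (1.37) adjusted over the list alone. All 20 interferon response genes were above 0 (median 0.86, adjusted p = 8.4e-09; adjusted p = 0.249 with an estimated correlation), with 8 higher adjusted over the list alone, such as Irf7 (1.5) and Rsad2 (1.95). All 26 cell cycle genes were below 0 (median −1.49, adjusted p = 1.0e-09; adjusted p = 0.474 with an estimated correlation), with 7 lower adjusted over the list alone, such as the mitotic kinase gene Aurkb (−2.90).

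Markers of other cells moved with this library as well. T cell markers were lower (median −1.57, adjusted p = 4.1e-12; adjusted p = 0.249 with an estimated correlation), with 12 of 20 lower adjusted over the list alone, and Cd3d stood at 0.39 CPM against 4.81 and 3.51 CPM. In the unblocked fit this was the single list of the comparison still called (adjusted p = 0.0352 with an estimated correlation). NK markers were lower (median −1.57, adjusted p = 8.0e-06; adjusted p = 0.249 with an estimated correlation). All 8 erythroid markers were higher (median 1.43, adjusted p = 0.000216; adjusted p = 0.474 with an estimated correlation), with the beta-globin gene Hbb-b1 at 1410.40 CPM against 362.27 and 122.46 CPM.

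The series implies a test of whether genes moved in opposite directions in FO cells labelled as lacking Ebf1 and with Cd79a-Cre. Ebf1 itself was not lower in the library labelled Cd23-Cre Ebf1(fl/–) (0.76 with the series term, and called higher at 0.82 ± 0.16 in the bias-score fit, adjusted p = 0.0267). Its difference with Cd79a-Cre passed no test adjusted over all genes (edgeR with the series term, unadjusted p = 0.0312 in FO and 0.0489 in B-1a cells). The directions below therefore follow the labels and not a called change of Ebf1. Of the 43 genes called in the library labelled Cd23-Cre Ebf1(fl/–), 31 (72.1%, exact Clopper-Pearson 95% interval 56.3 to 84.7) had the opposite sign with Cd79a-Cre in B-1a cells, against 42.4% of all genes. The groups compared share no library, but the series term is estimated from all 9 libraries, and unchanged groups gave a simulated r of 0.103. Genes are not independent replicates, so the intervals and Fisher tests here and below cover no spread between animals. Epcam (−3.09 there, 1.18 with Cd79a-Cre), the adhesion gene Pvrl1 (−3.95 and 1.70) and Extl1, a glycosyltransferase gene, were called lower there and higher in B-1a Cd79a-Cre cells. These 3 genes compare with 0.0520 expected of independent lists (Fisher's exact test, p = 1.8e-05), and 0 genes were called in any other combination. Extl1 had 0 counts in the library labelled Cd23-Cre Ebf1(fl/–) against 272 in the FO controls (at least 21.7-fold lower). In FO cells 36 of 43 (83.7%, interval 69.3 to 93.2) had the opposite sign, against 60.8% of all genes.

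In the bias-score fit Epcam, Plac8, Sema7a and Sh2b2 were called lower in the library labelled Cd23-Cre Ebf1(fl/–) and higher with Cd79a-Cre in FO cells, 4 genes against 0.0932 expected of independent lists (Fisher's exact test, p = 1.0e-06). Il9r was called higher in the former and lower with Cd79a-Cre (1 against 0.0151, Fisher's exact p = 0.0150), and Cd79a was lower in both (1 against 0.0266), a direction that the shared FO controls favour. Across all 11420 genes, which are not independent replicates, the log2 changes of the library labelled Cd23-Cre Ebf1(fl/–) and of Cd79a-Cre in FO cells had r = −0.0335 with the series term, where unchanged groups sharing the FO controls gave 0.167 (0.104 to 0.222), and a covariance of −0.0138 against a simulated 0.0426. With Cd79a-Cre in B-1a cells r was −0.00436 (simulated 0.103) and the covariance −0.00227 (simulated 0.0267). The Spearman correlations with the series term were −0.209 in FO and 0.107 in B-1a cells. By rank, the genes as a whole thus did not move in opposite directions in B-1a cells. There the Spearman correlation was 0.253 unblocked and −0.0367 with the bias score. Spearman correlations of unchanged groups were not simulated.

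**Figure D2:**
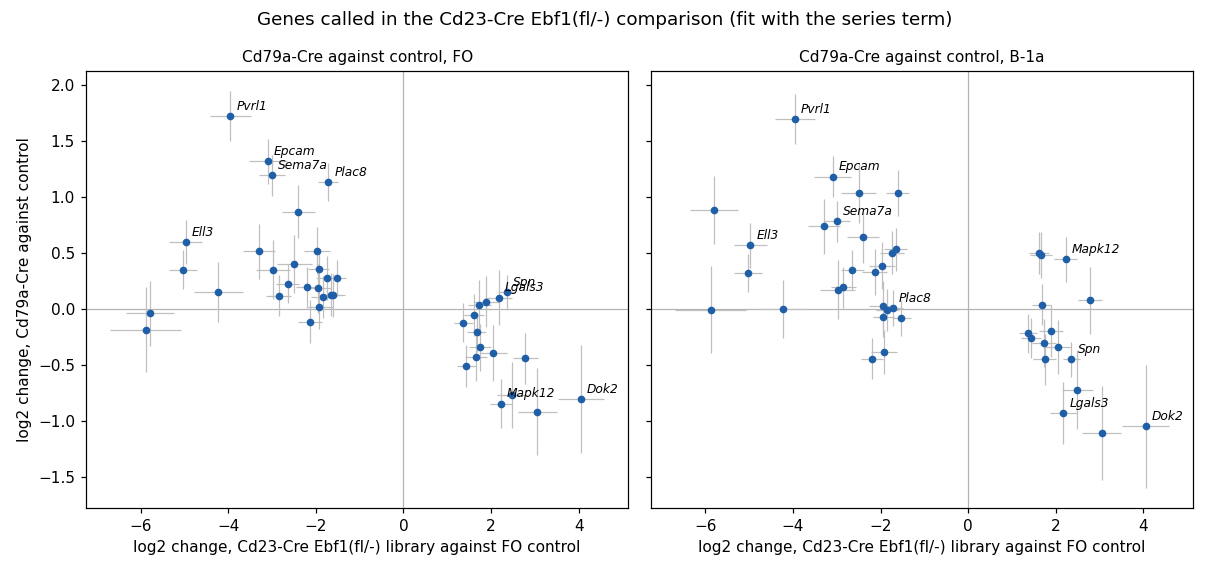
The log2 change in the library labelled Cd23-Cre Ebf1(fl/–) against FO controls (x axes) and with Cd79a-Cre against controls in FO (left) and B-1a cells (right; y axes), for the genes called in the former with the series term and more than 3 counts in their lower group, with bars for the SE. Opposite signs were seen for 36 of the 43 called genes in FO and 31 in B-1a cells.

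Genes that distinguish B-1a from FO cells were set against the response to Cd79a-Cre in FO cells. All 7 genes called higher with Cd79a-Cre in FO cells in the bias-score fit, Epcam, Sema7a and Plac8 among them, were also called higher in B-1a than in FO controls, against 1.08 expected of independent lists, and 1 was lower in both against 0.249. Across genes the unblocked r was 0.380, against 0.555 (0.501 to 0.618) for unchanged groups sharing the FO controls, and the covariance 0.188 against 0.0873. By r there was thus no excess, since it lay below every simulated value, whereas the covariance lay above its simulated mean. Both comparisons use the same 2 FO control libraries, which cannot be split with 2 left for each. The 7 genes were set against independent lists, which shared controls do not give. Part of the excess in that count and in the covariance may come from the shared controls. With 1 control library for each comparison, so that none is shared, the difference with Cd79a-Cre within series 1 and that of B-1a from FO within series 2 were 1.11 and 3.84 for Epcam, 0.93 and 2.88 for Sema7a, 1.28 and 2.20 for Plac8, and 0.44 and 1.86 for Sh2b2. These genes were named for their calls in all libraries, and the single-library differences carry no test. The called gene 4931429I11Rik was not higher with Cd79a-Cre within either series (−0.89 and 0.00). The log2 changes of the library labelled Cd23-Cre Ebf1(fl/–) set against B-1a minus FO gave r = −0.148 (simulated 0.185) and a covariance of −0.183 (simulated 0.0655).

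EBF1 binding in wild-type FO B cells was read from regions called separately in both ChIP libraries. Regions were ranked by the lower of the folds in both libraries. Of the first 10, that with the most reads lay on chromosome 6 at 94468001 to 94468800 (mm9), with 155 and 240 kept positions against 17 in the pooled input, or 46.1- and 42.8-fold over input. This is 0.00307% of positions (exact Clopper-Pearson 95% interval 0.00261 to 0.00359) and 0.00285% (0.0025 to 0.00323), against 6.29e-05% in input. Regions on chromosome 14 at 69896051 to 69896550 (49 and 60 positions against 5, 43.7- and 32.1-fold) and chromosome 8 at 14873751 to 14874200 (37 and 53 against 5, 33.0- and 28.3-fold) followed. Among the other 7 regions, 2 had 0 input positions, on chromosome 12 at 81102701 to 81103150 (14 and 32 ChIP positions) and on chromosome 9 at 78278251 to 78278600 (9 and 17). The remaining 5 had 1 input position each, on chromosome 10 at 127108301 to 127108750 (17 and 36) and chromosome 5 at 121669201 to 121669600 (16 and 20). The others of these lay on chromosome 16 at 20195601 to 20196050 (15 and 19), chromosome 2 at 127163701 to 127164100 (13 and 19) and chromosome 6 at 68252101 to 68252550 (12 and 18). Genes at these regions are not given because no mm9 annotation was used here.

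In total 615 regions were called in the first library and 1383 in the second, and 316 were shared (51.4% and 22.8%), with a median length of 400 bp. Of these, 27 lay where the input was over 5 times its genome mean, and their folds over input were only 0.819 to 1.49 and 0.651 to 1.18. The other 289 had median folds of 12.2 and 10.3, and folds of at least 4.12 and 2.94. Over all 316 regions the density was highest on chromosome 19 (15 regions, 0.245 per Mb) and, among autosomes, lowest on chromosome 13 (4 regions, 0.0333 per Mb). These counts are small, the 316 include the 27 regions of high input, and differences between chromosomes were not tested. Kept positions numbered 5046552 and 8429884, after 5.24% and 48.1% duplicates were removed. The 289 regions held 0.126% (0.123 to 0.129) and 0.0981% (0.096 to 0.1) of positions, against 0.00646 to 0.0111% in the input libraries, and all 316 held 0.175% and 0.134%, against 0.0425 to 0.0667%. The log2 folds of both libraries had a Pearson correlation of 0.655 and a Spearman correlation of 0.644 across the 289 regions, and 0.867 and 0.727 across all 316. Both folds divide by the same pooled input count, and the regions were selected as called in both libraries. The correlations therefore cannot show how far the ChIP libraries agree by themselves. Regions are not independent replicates. On simulated data the caller recovered 4% of 10-fold and 58% of 20-fold sites, so bound sites of such folds are missed. Not every called region need be bound. Input libraries called like a ChIP library gave 17 to 23 regions each that overlapped shared ones.

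**Figure D3:**
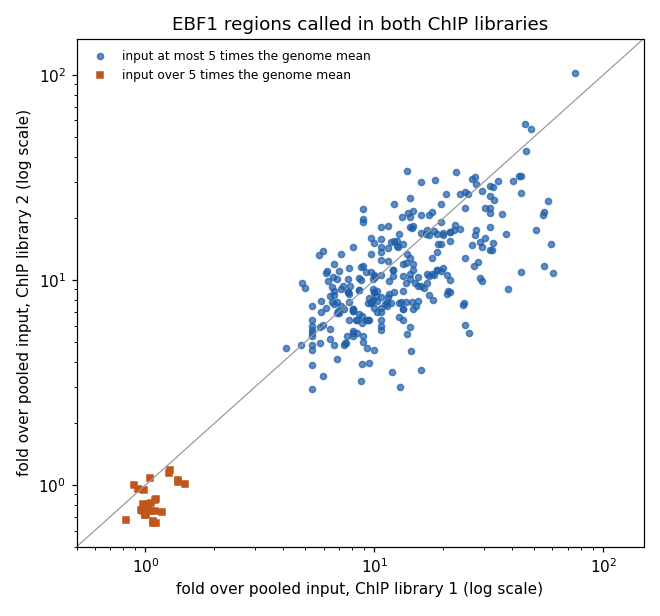
Fold over pooled input in the first (x axis) and second ChIP library (y axis), both on log scales, for the 316 shared regions, with the 27 regions of high input in orange and the line of equal folds in grey. The 27 regions lie near a fold of 1 in both libraries, and the other 289 have median folds of 12.2 and 10.3.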

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

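All tests of explanations here, and the bias-score fit, were chosen only after the results were seen.

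The response to Cd79a-Cre differed between the cell types in 13 named genes by a test of the difference itself (edgeR with the bias score, B-1a minus FO on the log2 scale, adjusted p under the threshold in each). The differences were −3.08 for Igf1r, −2.46 for Slc30a4, −2.34 for Kif13a, −2.27 for Ngfrap1, −2.26 for Ipcef1, −2.14 for Stat4, −1.84 for Gpr171, −1.71 for Satb1, −1.69 for Actn1, −1.59 for Smad7, −1.32 for Atp1b1, −0.92 for Plac8 and 1.3 for Hpse. The unblocked and series-term fits of edgeR called 0 genes for this difference. They had 128 and 551 at an unadjusted p under 0.05, fewer than chance alone gives. DESeq2 called Igf1r and Kif13a without the series term, and 3 higher and 20 lower with it. On simulated data the bias-score fit made 19 false calls for this difference. It also recovered 33, 48 and 60 genes changed 2-, 4- and 8-fold there. That simulation contained changed genes, so its 19 false calls do not give the number of false ones among the 15 calls here. Some of the 15 may be false, so the 13 genes are candidates.

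Among the 5 input libraries, library 8042, the single library with 4 runs, gave 3333 called regions when treated like a ChIP library, while the others gave 62 to 72. Its gap to the nearest library was 0.997 of the whole range. Chance flags about 1 in 20 groups in this way, and 5 quantities were tested. Library 8042 also had the most kept positions, 10075998 against 3584351 to 5248047, and the counts were not compared at equal depth. It supplied 10075998 of the 27034026 positions of the pooled input behind the region calls.

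Ebf1 reads in the library labelled Cd23-Cre Ebf1(fl/–) were not below the FO controls (443 CPM against 233 and 330 CPM). That the library is a further FO control with intact Ebf1 stays open, since 1 library decides nothing, although 72.1% of the genes called in it had the opposite sign with Cd79a-Cre in B-1a cells, against 42.4% of all genes. Reads from outside the deleted part may still be counted, and the whole-gene log2 change of 0.76 leaves this open because exon counts were not analysed here. A biological rise of transcript from the remaining allele stays open and was not tested.

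Cd79a was lower in both Cd79a-Cre groups. The library series alone is argued against, since all 4 differences within a series were negative and the one closest to 0 was −0.64. The Cre insertion may remove the reads of 1 Cd79a allele, which would give a log2 change of −1, but while the value farthest from that in standard errors, −0.71 ± 0.17 in B-1a cells, lies within 2 of them, so does the −0.69 ± 0.21 of the library labelled Cd23-Cre Ebf1(fl/–), which carries no Cd79a-Cre by its label, so this test leaves the insertion open. Whether EBF1 from the transgene also lowers Cd79a cannot be told apart from the insertion, because every library with the transgene switched on carries Cd79a-Cre. Cd79b, the partner chain, had a change of 0.014 ± 0.16 in FO cells and of 0.37 ± 0.16 in B-1a cells (0.41 and 0.33 within the series).

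Of the 43 genes called in the library labelled Cd23-Cre Ebf1(fl/–), 31 had the opposite sign with Cd79a-Cre in B-1a cells and 36 in FO cells. Shared FO controls are argued against, since they push both comparisons the same way and the observed covariance of −0.0138 lies below every simulated value (0.0268 to 0.0623). Strain differences of the single library stay open whatever the share of opposite signs (72.1% in B-1a cells), because strain label and genotype cannot be separated in 1 library. Of the calls of the bias-score fit, 66.4% (exact Clopper-Pearson 95% interval 60.0 to 72.4) were opposite, against 50.6% of all genes. That leaves the library bias open, because the score also holds differences between groups and the single library's own difference from the others. Whether the amount of EBF1 sets the level of these genes stays open and was not tested. Ebf1 reads were not lower in that library, and the Ebf1 difference with Cre passed no test adjusted over all genes.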

How the results depend on the processing

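The bias-score fits, the count without places of high input, the correlations with the series term, and the DESeq2 fits, RLE scaling and leave-one-out runs with the series term were chosen after seeing the data, and the other settings were fixed beforehand. Counts are higher and lower calls in this order: Cd79a-Cre in FO cells, Cd79a-Cre in B-1a cells, B-1a against FO, the same with Cre, the difference between Cre effects, and the library labelled Cd23-Cre Ebf1(fl/–). The unblocked edgeR counts were 0 and 0, 0 and 0, 236 and 117, 240 and 173, 0 and 0, and 0 and 0.

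DESeq2 called 1 and 0, 16 and 31, 553 and 338, 610 and 418, 0 and 2, and 17 and 29. The bias score gave 7 and 2, 61 and 120, 1757 and 1419, 1552 and 1715, 1 and 14, and 86 and 152. With the series as a replicate block, edgeR called 0 and 0, 22 and 30, 929 and 674, 1020 and 890, 0 and 0, and 16 and 27. The lists called by camera in the same order numbered 2, 5, 8, 8, 1 and 6 unblocked, 2, 4, 9, 9, 0 and 8 with that pairing and 2, 4, 8, 6, 6 and 8 with the bias score. DESeq2 with the series term called 11 and 2 for Cd79a-Cre in FO cells, 55 and 90 in B-1a cells, 3 and 20 for the difference, and 61 and 99 for the library labelled Cd23-Cre Ebf1(fl/–). The 3 were Cacna1h (2.61), Fstl1 (3.57) and Ggh (1.84), and the 2 lower in FO cells were Cd79a (−1.12) and Il9r (−1.08), named after their values were seen. A tested fold of 1.5 left 142 and 61 for B-1a against FO, by its stricter null. Fits of the compared groups alone, with fewer libraries for the spread, gave 89 and 24 for B-1a against FO, 115 and 71 with Cre, and 1 and 4 for the library labelled Cd23-Cre Ebf1(fl/–). Without a filter 1 gene was lower there. For the other differences the cause was not tested.

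Leaving out 1 library moved the counts widely. For B-1a against FO the range was 4 to 35 higher and 0 to 34 lower, with 5 and 4 without the first FO control, 35 and 34 without the second, 4 and 0 without the first B-1a control and 28 and 3 without the second. With Cre the range was 0 to 156 higher and 0 to 67 lower, with 0 and 0 without either FO library, 77 and 31 without the first B-1a library and 156 and 67 without the second. In such fits the lone library is assumed to vary like the other groups, and fewer samples by construction lower the power. With the series term the ranges were 1 to 10 and 1 to 20 for Cd79a-Cre in B-1a cells, with 1 and 1 without the first B-1a control, 5 and 3 without the second, 4 and 2 without the first B-1a Cd79a-Cre library and 10 and 20 without the second. They were 566 to 687 and 297 to 492 for B-1a against FO, with 573 and 356 without the first FO control, 566 and 297 without the first B-1a control and 583 and 317 without the second. With Cre they were 587 to 747 and 395 to 672, with 587 and 444 without the first FO library, 641 and 395 without the first B-1a library and 514 lower without the second. They were 0 to 1 and 0 to 4 for the difference, with 4 lower without the second FO control and 1 and 1 without the second B-1a Cd79a-Cre library, and 9 to 14 and 14 to 42 for the library labelled Cd23-Cre Ebf1(fl/–), with 9 and 14 without the first FO control and 42 lower without the second.

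With an estimated correlation, the lists called by camera fell to 0 in the first 5 comparisons and to 1 for the library labelled Cd23-Cre Ebf1(fl/–). The correlation of the log2 changes in the library labelled Cd23-Cre Ebf1(fl/–) and with Cd79a-Cre in FO cells was −0.0838 unblocked, −0.0335 with the series term and 0.013 with the bias score, a change of sign, and the cause was not tested. Scaling by library totals put the median log2 change of all genes in the library labelled Cd23-Cre Ebf1(fl/–) at −0.16, against −0.035 with TMM. RLE and total-count scaling changed no count of calls by over 1.5 times.

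For ChIP-seq, 316 shared regions became 203 at a q of 0.00001, 571 with the genome-wide rate alone, 1198 in the pooled libraries, and 615 and 1383 in single libraries. Of 1682 regions called in either library, edgeR called 642 higher in ChIP than in input, a count of another kind. Without places of high input, an alternative added after seeing the data, 289 remained. The remaining settings gave 254 to 463 shared regions. The bound share of called genes and the EBF1 motif were not run, because no mm9 genome or annotation was used here. The unblocked fit recovered 0% of simulated 2-fold changes in each comparison. On the same libraries the series-term fit recovered 4.48 to 34.3% and the bias-score fit 49.3 to 73.1%, so depth and the number of libraries alone do not set the low unblocked counts.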

Other observations

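All tests here were chosen only after the values were seen.

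Neutrophil transcripts followed the library series in every group. All 9 members of the neutrophil list were higher in series 2 in all 4 groups, with median log2 differences of 3.16 in FO controls, 3.65 in FO Cd79a-Cre, 3.03 in B-1a controls and 2.88 in B-1a Cd79a-Cre. S100a9, a calcium-binding protein of neutrophils, had 1.12, 1.19, 0.98 and 0.73 CPM in series 1 and 23.38, 36.36, 15.05 and 12.28 CPM in series 2, although the cells were sorted by flow cytometry. Of 17 monocyte markers, 9 were higher in series 2 in all 4 groups and 0 were lower in all 4, with medians of 1.07, 1.33, 0.95 and 0.18 in the same order. The sex-linked list differed between series by −7.79 in FO Cd79a-Cre and −6.93 in B-1a Cd79a-Cre, and by 0.47 and 0.56 in the FO and B-1a controls. Differences with Cd79a-Cre within series 2 therefore also hold a difference in Y-linked reads.

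Of the platelet and megakaryocyte markers, 2 passed the expression filter, and Itga2b, the integrin alpha-IIb gene, lay between 0.52 and 2.36 CPM in the 9 libraries. Reads outside genes made up 13.5% of the library labelled Cd23-Cre Ebf1(fl/–), 12.8 and 25.7% of the FO controls, 18.2 and 21.2% of FO Cd79a-Cre, 20 and 37.1% of the B-1a controls and 14.6 and 31.6% of B-1a Cd79a-Cre, with the higher share in series 2 in each group of 2.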
